A study of Schizosaccharomyces pombe with 16 samples.

How the data were processed

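The series holds chromatin immunoprecipitation on 2-colour Agilent tiling arrays (ChIP-chip) of the fission yeast Schizosaccharomyces pombe. H3K9me2, the dimethylated histone H3 lysine 9 of heterochromatin, was measured in wild type smt0, wild type h+ and strains with a deletion of mmi1, erh1 or ccr4. Erh1 with a GFP tag was measured in wild type and in the mmi1 deletion, and Mmi1 with a CFP tag in wild type. Each of these 8 groups has 2 arrays, 16 in all. Per the labels, cells grew in rich medium to logarithmic phase and were fixed with paraformaldehyde, the tagged strains also with DMA. ChIP DNA was labelled with Cy5 and whole-cell extract DNA, the input, with Cy3. The series design calls the arrays biological replicates; the sample labels do not say that the replicates are separate cultures. The p-values measure the spread between these arrays, which may be technical.

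Per the file headers, the authors' scanner files came from Agilent Feature Extraction 10.7.3.1, 11.0.1.1 or 11.5.1.1. The processed signal of each spot and channel in the deposited files was used as intensity; per the file headers that software had subtracted the background, fitted a spatial trend and normalized the dyes within the array. Dye normalization used a linear factor on 13 arrays and also lowess on 3, which were CFP-Mmi1 replicate 1, wild type h+ replicate 2 and ccr4 deletion replicate 2. The deposited 0 or 1 flags for outlier spots and for signals well above background, of unit other, were used as filters. The log10 column per the file headers is the log10 of the red over the green processed signal and served only to check the direction of the ratio. The authors also deposited a table of the linear ratio of ChIP to input per probe. In that deposited table the 2 columns of wild type smt0 are exchanged relative to the scanner files, and the column of Erh1-GFP wild type replicate 1 matches no scanner file of the series. The scanner files were therefore used, and the table served as an alternative. The genome build behind the probe positions is not given in the sources used here.

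For each spot, log2 of the red over the green processed signal was taken, so that positive values mean more ChIP than input. Spots that the software marked as outliers were left out, and each array was centred on the median of its 41551 non-control probes, so that 0 is the array median. An untagged strain was not analysed here, so that enrichment was measured against the array median alone. Of the probes, 41251 lie on the chromosomes, 300 bases apart. A probe was used where the input channel was well above background on every array of the fit, which removed 25 probes from the H3K9me2 fit and 11 from the tagged-protein fit. The input channel passed this test for at least 99.97% of probes on every array, and the ChIP channel for at least 94.3%. The number of arrays limits the precision.

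Gene positions came from assembly ASM294v3. The probe positions did not match that assembly, so the offset of each chromosome arm was found by correlating the GC content of 60-base windows at the shifted positions with the mean input signal. The offsets over the 6 arms ran from -1662 to 4465 bases, and all 48 windows of 250 kb lay within 200 bases of the offset of their arm. The lowest correlation at the chosen offset of an arm was 0.303, and 200 bootstrap draws over blocks of 50 kb gave its spread. This match was made after the data were examined and departs from the plan of not combining coordinates of different builds. It served to assign probes to genes. Through the gene positions it also set the bounds of the pericentromeres and of the silent mating-type region, and so which domains count as islands. All coordinates printed are array coordinates of probe starts. Of 5113 protein-coding genes on the chromosomes, 5102 had a probe and 4953 at least 2, with a median of 6 probes per gene. The noncoding gene sme2 was added as a list member. Genes whose input signal in a group lay at least 2 on the log2 scale below that of the other groups were taken as missing and left out of the fit: mmi1, erh1, ccr4, ura4 and SPAC212.06C from the H3K9me2 fit, and mmi1 and ura4 from the other. Means over the probes of each gene were tested for 4940 genes in the H3K9me2 fit and 4951 in the tagged-protein fit.

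Differences were tested with limma 3.58.1 in R 4.3.3. One linear model covered the 10 H3K9me2 arrays and another the 6 arrays of tagged proteins, with group as the only term. The residual degrees of freedom were 5 and 3, and the prior degrees of freedom 4.97 and 5.05. Each deletion was compared with the mean of both wild types, since the series design does not say which wild type belongs to which deletion. The wild types were also compared with each other, and the deletions with one another. Tests were two-sided with the Benjamini-Hochberg adjustment over genes, and a gene was called at an adjusted p under 0.05. A gene was called enriched for a tagged protein at a one-sided adjusted p under 0.05 and a mean at least 1.5-fold above the array median. The labels give the arrays of each group the replicate numbers 1 and 2. On the arrays of tagged proteins, same-numbered arrays deviated from their group means together, with correlations across genes of 0.31, 0.35 and 0.69 over the 3 pairs of groups, and the replicate 2 arrays shared slide 5, so the numbers were taken to pair these arrays. The fit without the block stayed the one reported, as fixed before, and the blocked value is given where it moves a call. SD is over the 2 arrays of a group, and SE is the moderated standard error from limma.

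H3K9me2 domains were runs of at least 3 probes whose running median over 5 probes, taken on the mean of the 5 groups, was at least 1.5-fold above the array median. Runs less than 1 kb apart were joined. This gave 139 domains. Of these, 124 outside the constitutive heterochromatin are called islands. The other 15 lie in subtelomeres (9), pericentromeres (3), the mating-type region (1) and the ends of chromosome III (2). Domain means were tested with limma over all 139 domains.

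Gene lists were written before the data were examined, as were the comparisons, their tests, the thresholds, most other settings tried and the rule for named genes. The 9 lists, with members fixed and members measured in the H3K9me2 fit, were the Mmi1 target list (11 and 11), other meiotic genes (24 and 24), phosphate genes (3 and 3), Tf2 retrotransposons (13 and 11), subtelomeric genes of the outer 50 kb of chromosomes I and II (70 and 50), genes of the silent mating-type region and pericentromeres (2 and 1), ribosomal protein genes (131 and 113), glycolytic and other strongly transcribed genes (20 and 20), and RNA elimination and heterochromatin factor genes (16 and 16). The tagged-protein fit measured 51 subtelomeric and 114 ribosomal protein genes. The symbol mcp5 of the target list is num1 in the annotation. Lists with at least 2 measured members were tested with camera of limma, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The rule named, for each deletion, all measured members of the target list, up to 10 rises and 10 falls past the threshold with both deletion arrays on one side of every wild-type array, up to 2 rises and 2 falls of each other list, and every called island. For enrichment it named the 15 highest means among called genes. Regions were given boundaries, and the ends of chromosome III and the segment beside the silent mating-type region were singled out, after the data were examined.

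The pipeline was tested on simulated data with changes planted in a known set of genes. In the simulation of the mmi1 comparison of H3K9me2 over 4940 genes, 5 of 67 genes shifted by 1 on the log2 scale were called, 46 of 67 shifted by 2, 64 of 66 shifted by 3, and 5 unchanged genes. In that of the ccr4 comparison, 3 of 67, 49 of 67 and 66 of 66 were called, and 0 unchanged genes by the same limma test. In that of Erh1-GFP over 4951 genes, 62 of 67, 67 of 67 and 66 of 66 were called, and 10 unchanged genes. Of 40 planted domains, 40 were found among 41 called.

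The other settings written before the data were examined were normexp background correction with an offset of 50, loess within arrays with a span of 0.3, the deposited table, no probe filter, the replicate number as a block, slide as a random block, leaving out each array, the probe median, at least 4 probes per gene, either wild type alone, fits with the wild types and 1 deletion alone, scaling each array by its mean over pericentromeric and subtelomeric domains, an added 1.5-fold threshold, camera with an estimated correlation, and thresholds of 1 for domains and enrichment. Because the scaling draws on the subtelomeric domains, it can offset or turn a change at subtelomeric genes and is no independent check there. The scanner files hold no mean signals, so normexp was run on median signals and their local background medians. Examined only after the results were seen were the ranges of the Erh1-GFP list means without single arrays and the pericentromeres within slides. Chosen after the data were examined were leaving out or down-weighting the 3 arrays of slide 1, slide as a fixed block with the wild type of the same slides, keeping outlier spots, and leaving out the arrays with lowess dye normalization. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.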

Results

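ChIP-chip arrays of S. pombe measured where histone H3 carried dimethylated lysine 9 (H3K9me2) and where Erh1-GFP and CFP-Mmi1 sat on the chromosomes. Mmi1 is an RNA-binding protein of the YTH family that removes meiotic transcripts from growing cells, Erh1 is its partner, and Ccr4 is a deadenylase of the Ccr4-Not complex. The H3K9me2 arrays fall into 5 groups of 2: wild type smt0, wild type h+, mmi1Δ, erh1Δ and ccr4Δ. The tagged proteins give 3 more groups of 2: Erh1-GFP in wild type, Erh1-GFP in mmi1Δ and CFP-Mmi1 in wild type. Each array carries 41551 probes. Levels are log2 of ChIP over input relative to the array median, with the SD over n = 2 arrays, and changes carry the SE and adjusted p of limma. The number of arrays limits the precision. Positions are array coordinates of the first and last probe start, and the genome build behind them is not given in the sources used here. The arrays sat on 7 slides. The 3 arrays of slide 1, which are wild type smt0 replicate 1, mmi1Δ replicate 2 and erh1Δ replicate 2, spread wider over genes, with a median absolute deviation of 1.19, 0.75 and 0.91 against 0.22 to 0.44 on the other H3K9me2 arrays.

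The first question of the series design is how H3K9me2 differs between mmi1Δ and wild type. In the mmi1Δ strain H3K9me2 was lower at mei4 (SPBC32H8.11, II 1473900 to 1476000, 7 probes), which encodes the forkhead transcription factor of meiosis. Its level was 3.81 ± 0.55 in wild type smt0, 3.33 ± 0.28 in wild type h+ and 0.17 ± 0.51 in mmi1Δ. The change against the mean of the wild types was -3.40 (SE 0.40, adjusted p = 0.0179), a level 10.6-fold lower. A further mei4 probe (II 1475400) was missing from the input of both mmi1Δ arrays, at -7.42 relative to the median of the arrays, and was left out. This strain thus differs from the wild types at that probe. For the fall at mei4, loss of mmi1 and this change of the mei4 locus cannot be told apart in mmi1Δ. H3K9me2 also fell at ssm4 (SPAC27D7.13C, I 4530300 to 4532100, 7 probes), a dynactin subunit of meiotic nuclear movement, from 3.08 ± 0.12 and 2.45 ± 0.37 in the wild types to 0.02 ± 0.12. That change was -2.74 (SE 0.30, adjusted p = 0.0179), 6.69-fold. These were the 2 genes called of 4940, both lower, beside 294 at an unadjusted p under 0.05. Within slide 1, mmi1Δ lay below wild type smt0 by -2.90 at mei4 and -2.89 at ssm4.

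Among the other Mmi1 targets, mcp7, which acts in meiotic recombination, had 2.02 ± 1.45 and 2.73 ± 0.85 in the wild types and -0.60 ± 0.14 in mmi1Δ. Its change of -2.97 (SE 0.60) missed the threshold over all genes (adjusted p = 0.280). The dynein anchor num1, also called mcp5, had 2.01 ± 0.45 and 1.48 ± 0.64 in the wild types and -0.14 ± 0.23 in mmi1Δ (adjusted p = 0.390). Adjusted over the list alone, 4 members fell: mei4, ssm4, mcp7 and num1. The values of mug9, mug8 and the noncoding RNA gene sme2 were -1.45, -0.87 and -0.41, and those of mug10, crs1, the meiotic cohesin rec8 and spo5 lay between -0.12 and 0.12. As a group the 11 targets were lower by a mean of -1.26 (camera adjusted p = 1.58e-06; adjusted p = 0.0224 with an estimated correlation), and by -1.37 within slide 1.

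In mmi1Δ no other list passed the threshold with an estimated correlation. Of the 24 other meiotic genes 0 fell over all genes by limma and 3 adjusted over the list alone, with a mean of -0.34 (camera adjusted p = 0.202). The 50 subtelomeric genes had a mean of -0.48 (camera adjusted p = 0.0075, and adjusted p = 0.666 with an estimated correlation). This mean turned to 1.34 when arrays were scaled by their heterochromatin signal and to 0.31 under loess, and was 0.67 within slide 1. The scaling draws on the subtelomeric domains themselves, so it can offset or turn a change at these genes. The Tf2 retrotransposons, the phosphate genes and the ribosomal protein genes had means of 0.22, -0.32 and -0.30, with camera adjusted p from 0.158 to 0.506. The glycolytic and other strongly transcribed genes had -0.35, and the RNA elimination and heterochromatin factor genes a mean of 0.03 and a median of -0.01. The call of mei4 ended without wild type smt0 replicate 2, and those of mei4 and ssm4 without either array of mmi1Δ, wild type h+ or ccr4Δ. By limma 0 genes were called under normexp, loess, the replicate block or slide as a fixed block. The count was also 0 with only the wild types and mmi1Δ in the fit and after scaling by heterochromatin signal. With slide 1 weighted apart 427 were called (419 lower). Without slide 1, mmi1Δ keeps 1 array, which is the only array on slide 3. In that setting the deletion and the slide cannot be told apart.

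**Figure D1:**
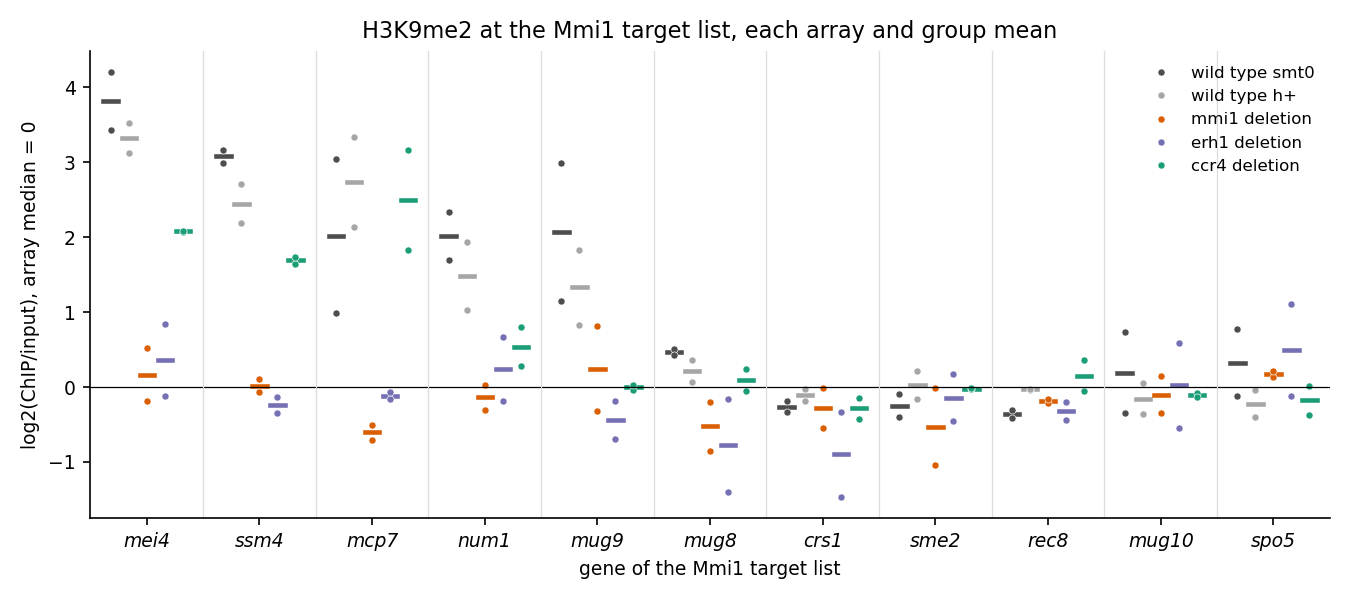
H3K9me2 (log2 ChIP over input, array median 0) at the 11 genes of the Mmi1 target list, with 1 point per array and a bar at the mean of each of the 5 groups. At mei4 and ssm4 the mmi1Δ and erh1Δ means lie between -0.23 and 0.36, and those of the wild types between 2.45 and 3.81.

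The same question was asked of erh1Δ. Loss of erh1 lowered H3K9me2 at the same pair of meiotic genes, mei4 and ssm4. At mei4 the level was 0.36 ± 0.68, lower by -3.21 (SE 0.40, adjusted p = 0.0297), or 9.27-fold. At ssm4 it was -0.23 ± 0.15, 7.98-fold lower (SE 0.30 on the log2 scale, adjusted p = 0.0093). No other gene of 4940 was called, beside 171 at an unadjusted p under 0.05. Against wild type smt0 on slides 1 and 2, mei4 lay at -3.55 and -3.37 and ssm4 at -3.33 and -3.29.

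Of the 11 Mmi1 targets 2 fell over all genes and 6 adjusted over the list alone: mei4, ssm4, mcp7, mug9, num1 and mug8. The level of mcp7 was -0.11 ± 0.06 in erh1Δ, a change of -2.49 (adjusted p = 0.695), and that of mug9 was -0.44 ± 0.36, a change of -2.14 (adjusted p = 0.893). The changes at num1, mug8 and the meiotic cyclin gene crs1 were -1.51, -1.12 and -0.72, while rec8, sme2, mug10 and spo5 lay between -0.12 and 0.44. The list mean was -1.26 (camera adjusted p = 2.72e-08; adjusted p = 0.0138 with an estimated correlation), with -1.45 and -1.26 within slides 1 and 2.

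In erh1Δ the 50 subtelomeric genes had a mean of -0.93 (camera adjusted p = 1.08e-11; adjusted p = 0.783 with an estimated correlation). Of these, 0 fell over all genes by limma and 9 adjusted over the list alone, and the means within slides 1 and 2 were -0.91 and -0.65. The other meiotic genes, phosphate genes, Tf2 retrotransposons and ribosomal protein genes had means of -0.20, 0.19, 0.29 and -0.22, with camera adjusted p from 0.115 to 0.636. The mean of the glycolytic and other strongly transcribed genes was -0.03, with a median of 0.08, and turned to 0.26 under loess. The factor genes had a mean of 0.01 and a median of -0.06. Without either array of wild type h+ or ccr4Δ, or without erh1Δ replicate 2, the calls of mei4 and ssm4 ended. That of mei4 also ended without wild type smt0 replicate 2 or either mmi1Δ array, under loess or the replicate block and with smt0 alone; 19 genes were lower with slide 1 weighted apart and 5 with slide as a random block, and 0 were called by limma without slide 1, with slide as a fixed block, under normexp, with only the wild types and erh1Δ in the fit, after scaling or without the lowess arrays.

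Outside the bounds set for constitutive heterochromatin, 124 islands of H3K9me2 were found. Some lay near a pericentromere, such as those at I 3660900 to 3663900 and I 3843600 to 3871200, on either side of that of chromosome I (I 3752700 to 3786300). The same 4 islands fell in mmi1Δ and in erh1Δ, and all 4 lie over meiotic Mmi1 targets. The island over ssm4, with but1 and tpr1 (I 4529100 to 4532700), changed by -2.44 (SE 0.38, adjusted p = 0.000972) in mmi1Δ and by -2.47 (adjusted p = 0.000818) in erh1Δ. The island over mcp7 and ubp8 (I 579000 to 581100) changed by -2.73 (adjusted p = 0.00458) and -2.27 (adjusted p = 0.0145), and that over num1 (II 900000 to 901800) by -2.27 (adjusted p = 0.00801) and -1.93 (adjusted p = 0.0225). The island over wdr8, cdk9, mei4, act1 and mok12 (II 1468200 to 1479000) changed by -1.62 (adjusted p = 0.0364) in mmi1Δ and was also lower in erh1Δ (adjusted p = 0.0479). It holds the mei4 locus that was altered in the mmi1Δ strain. The mug9 island (III 2370000 to 2370900) had -1.35 and -1.82 (adjusted p = 0.435 and 0.0753). Both deletions were set against the same wild types. In 100 simulations in which no island changed in any group, 0.02 shared islands were found on average. With nothing changed, few islands can be called at all, and the noise was drawn apart for each array, without shared slides. The simulation therefore cannot tell how far the shared control aligned the calls. Splitting the wild types between the deletions left 2 and 1 shared islands. Without either mmi1Δ array 1 island was called in mmi1Δ and 1 in erh1Δ, and without either erh1Δ array or wild type h+ replicate 2 there was 1 in erh1Δ. Without wild type smt0 replicate 2 there were 8 in each deletion (with 9 and 7 at an unadjusted p under 0.05 when all arrays were used); scaling by heterochromatin signal left 1 and 0 by limma, and with slide as a fixed block the islands over mcp7 and mei4 lost their call in mmi1Δ and that over mcp7 in erh1Δ.

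In erh1Δ H3K9me2 also fell at both ends of chromosome III. The left end (III 0 to 24600, 58 probes) had 3.28 ± 1.28 in wild type smt0, 3.05 ± 0.01 in wild type h+ and 0.48 ± 0.97 in erh1Δ, a change of -2.68 (SE 0.51, adjusted p = 0.00426). The right end (III 2440200 to 2453700, 21 probes) changed by -2.56 (SE 0.50, adjusted p = 0.00426). On each H3K9me2 array the ends had close values, with 1.17 and -0.20 at the left and 1.21 and -0.13 at the right in erh1Δ. Whether their probes share repeated sequence was not checked, so the calls at the left and right end may not be independent. The ends had 2.67 and 2.65 in mmi1Δ, changes of -0.49 (adjusted p = 0.605) and -0.45 (adjusted p = 0.614), and 1.20 and 1.29 in ccr4Δ (adjusted p = 0.155 for both). The direct differences between erh1Δ and mmi1Δ, -2.19 and -2.12, missed the threshold (adjusted p = 0.141). Without erh1Δ replicate 2 the changes were -1.99 and -1.89 (adjusted p = 0.215 and 0.227, within 3.82e-09 to 0.321 over all alternatives), and the calls also ended without either mmi1Δ array, with only the wild types and erh1Δ in the fit, and after scaling by heterochromatin signal.

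**Figure D2:**
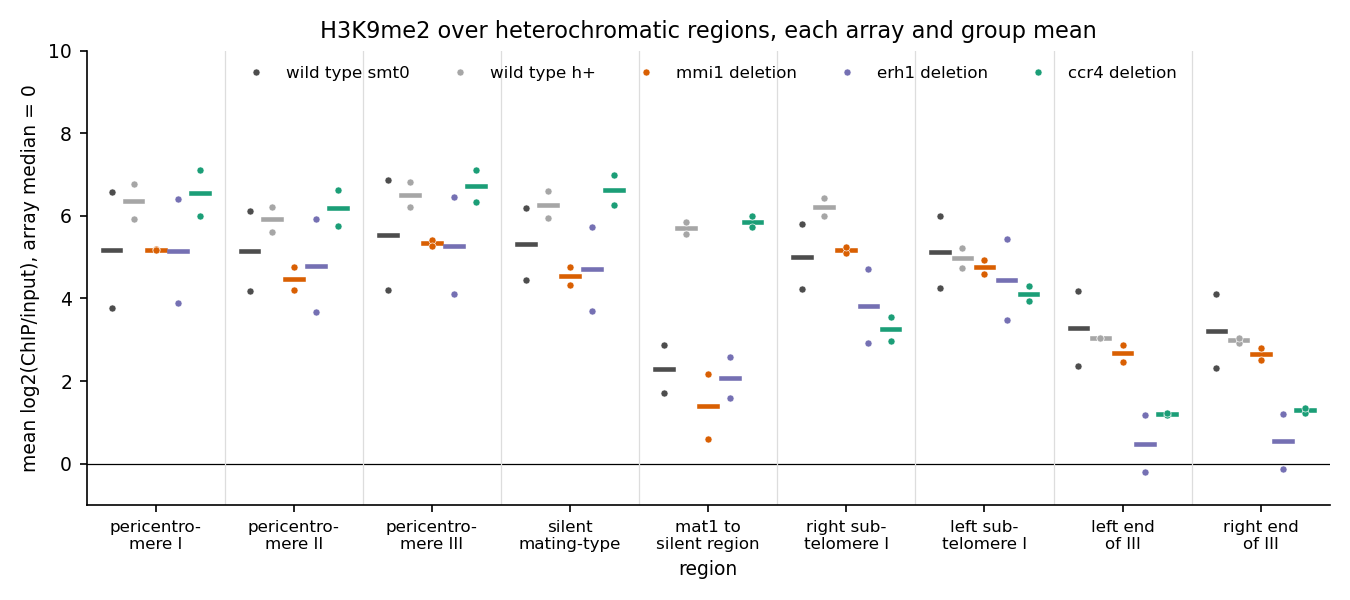
H3K9me2 (log2 ChIP over input, array median 0) over 9 regions of constitutive heterochromatin, with 1 point per array and a bar at the mean of each of the 5 groups. The left end of chromosome III has 0.48 in erh1Δ and 3.28 and 3.05 in the wild types.

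A further comparison of the series design set ccr4Δ against wild type. In ccr4Δ H3K9me2 was lower at 6 genes near the right end of chromosome I and 1 near its left end. The aldo/keto reductase family gene SPAC750.01 (I 5551200 to 5552100) went from 5.96 ± 0.65 in wild type smt0 and 6.03 ± 0.02 in wild type h+ to 2.23 ± 0.10, a change of -3.76 (SE 0.37, adjusted p = 0.00457), or 13.6-fold. The L-lactate dehydrogenase gene SPAC186.08C (I 5544600 to 5545500) changed by -3.69 (SE 0.44, adjusted p = 0.0143), or 12.9-fold. Its neighbours SPAC186.07C, a hydroxyacid dehydrogenase, and pdc102 (SPAC186.09), of the pyruvate decarboxylase family, changed by -3.65 and -3.58 (adjusted p = 0.0353 and 0.0429). The uncharacterized SPAC186.04C and the isomerase SPAC186.06 changed by -2.94 and -2.89 (adjusted p = 0.0178 and 0.0173). There the wild types lay apart, at 3.99 ± 0.51 and 4.32 ± 0.57 in smt0 and 6.56 ± 0.12 and 6.31 ± 0.15 in h+, against 2.34 ± 0.07 and 2.42 ± 0.46 in ccr4Δ. At the left end of the chromosome, the aldo-keto reductase family gene SPAC977.14C (I 60600 to 61500) changed by -3.52 (SE 0.36, adjusted p = 0.00457), to 1.71 ± 0.01 in ccr4Δ. These 7 were the genes called of 4940, all lower, beside 59 at an unadjusted p under 0.05. Their input lay 0.78 and 1.31 above the wild types on the ccr4Δ arrays, so part of each fold change of the ratio may come from the input. The erh1Δ levels at the 7 lay between 2.72 (SPAC186.07C) and 4.35 (SPAC750.01), and SPAC186.04C, SPAC186.06 and SPAC186.07C were called lower in erh1Δ with slide as a random block.

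Of the 60-base windows of SPAC750.01 and SPAC977.14C, 30.3% and 26.9% occur elsewhere in the reference. The 50 subtelomeric genes had a mean of -1.44 in ccr4Δ (camera adjusted p = 2.52e-51; adjusted p = 0.117 with an estimated correlation), with 6 fallen over all genes and 22 adjusted over the list alone. Against wild type h+ on slides 4 and 7 this mean was -1.55 and -1.61, and SPAC750.01 had -3.74 and -3.86. The right subtelomere of chromosome I (I 5524800 to 5574600) had 5.01 ± 1.11 and 6.22 ± 0.30 in the wild types, 5.17 ± 0.09 in mmi1Δ, 3.82 ± 1.28 in erh1Δ and 3.26 ± 0.40 in ccr4Δ. The wider domain (I 5444700 to 5574600) had a change of -1.43 in ccr4Δ (adjusted p = 0.325). This domain is among those used to scale arrays by heterochromatin signal, so that scaling can offset a fall at its genes.

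Of the Mmi1 targets, mei4, ssm4 and mcp7 carried H3K9me2 in ccr4Δ, at levels of 2.08 ± 0.01, 1.69 ± 0.06 and 2.50 ± 0.94. The level was 0.54 ± 0.37 at num1 and lay between -0.29 (crs1) and 0.15 (rec8) at the other 7. The list mean was -0.51 (camera adjusted p = 2.38e-05; adjusted p = 0.0441 with an estimated correlation), with -0.32 and -0.51 within slides 4 and 7. None of the 11 fell over all genes by limma, and 4 did adjusted over the list alone: mug9 (-1.70), mei4 (-1.49), num1 (-1.21) and ssm4 (-1.07). The others lay between -0.25 at mug8 and 0.35 at rec8, with 0.12 at mcp7. Against wild type h+ on slides 4 and 7, mei4 had -1.06 and -1.44 and ssm4 -0.54 and -0.97. The islands over ssm4, num1 and mcp7 had -0.94 (adjusted p = 0.573), -1.46 (adjusted p = 0.254) and 0.07, and 0 islands were called by limma, with 5 at an unadjusted p under 0.05.

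Among the other groups in ccr4Δ, the Tf2 retrotransposons had a mean of -0.63 (camera adjusted p = 9.23e-06; adjusted p = 0.383 with an estimated correlation), which was 0.27 without ccr4Δ replicate 2. The other meiotic genes, phosphate genes, ribosomal protein genes, glycolytic and other strongly transcribed genes, and factor genes had means of -0.09, -0.14, 0.17, 0.19 and -0.01, with camera adjusted p from 0.186 to 0.518. The calls of SPAC750.01 and SPAC977.14C ended without either ccr4Δ array, and those of the other 5 genes also under the replicate block, with smt0 alone or without either array of mmi1Δ or wild type h+; SPAC186.04C was also lost without wild type smt0 replicate 2, and SPAC186.07C and pdc102 without either smt0 array. By limma 0 genes were called under normexp or loess, after scaling, with only the wild types and ccr4Δ in the fit or without the lowess arrays; without slide 1 the count was 34 (31 lower), and with slide 1 weighted apart 65 (55 lower).

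**Figure D3:**
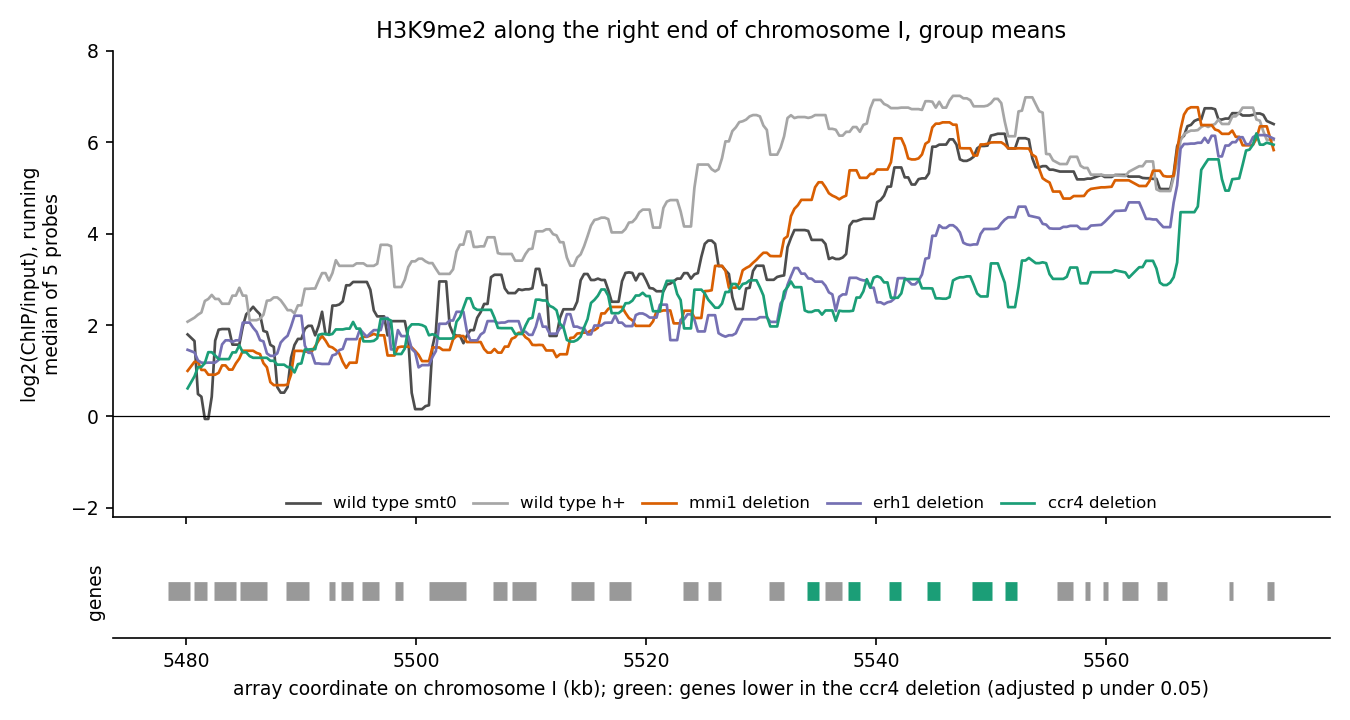
H3K9me2 along the right end of chromosome I, as the running median over 5 probes of the group mean (log2 ChIP over input, array median 0) against array position in kb, with 1 line per group. The genes lower in ccr4Δ are drawn in green, with SPAC750.01 at 2.23 in ccr4Δ and at 5.96 and 6.03 in the wild types.

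Direct comparisons of the deletions asked whether they differ from one another. Between erh1Δ and mmi1Δ 0 of 4940 genes differed by limma, with 155 at an unadjusted p under 0.05, and the Mmi1 target list had a mean difference of -0.01 (camera adjusted p = 0.960). The subtelomeric genes had -0.45 (camera adjusted p = 0.000933; adjusted p = 0.988 with an estimated correlation), which turned to 0.41 without erh1Δ replicate 2. Without slide 1, erh1Δ and mmi1Δ keep 1 array each, and that of mmi1Δ is the only array on slide 3. A difference between them in that setting cannot be told apart from one between slides. Between ccr4Δ and erh1Δ 0 genes differed by limma, with 140 at an unadjusted p under 0.05, and 43 differed with slide 1 weighted apart. The target list lay 0.75 higher in ccr4Δ (camera adjusted p = 0.00146, and adjusted p = 0.121 with an estimated correlation). The differences were 1.72 at mei4 and 1.93 at ssm4 (limma adjusted p = 0.891 and 0.304).

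Between ccr4Δ and mmi1Δ 11 genes differed, beside 337 at an unadjusted p under 0.05. By limma the count was 0 under normexp, loess or the replicate block and after scaling by heterochromatin signal. Those higher in ccr4Δ lie in the mating-type domain of chromosome II. They include the flavin oxidoreductase SPBC23G7.10C at 5.25 (SE 0.72), the DNA glycosylase mag2 at 5.16 (SE 0.76), the proteasome ATPase rpt6 at 4.22 (SE 0.60) and the translation initiation factor sui1 at 3.93 (SE 0.59). Those lower are SPAC186.08C, SPAC750.01, SPAC977.14C and SPAC186.06, from -3.75 to -3.03, and all 11 had adjusted p from 0.0265 to 0.0274. The level at SPBC23G7.10C was 1.49 ± 1.45 in wild type smt0, 1.37 ± 1.38 in mmi1Δ and 1.97 ± 0.24 in erh1Δ. It was 6.47 ± 0.16 in wild type h+ and 6.62 ± 0.18 in ccr4Δ. At this gene the wild types lay apart as ccr4Δ and mmi1Δ did. The level in ccr4Δ was near that of h+, and the level in mmi1Δ near that of smt0. The difference there thus need not come from either deletion. The series design does not say which wild type belongs to which deletion. The mcp7 island was 2.80 higher in ccr4Δ than in mmi1Δ (SE 0.60, adjusted p = 0.0269), and the target list 0.75 higher (camera adjusted p = 0.0112; adjusted p = 0.240 with an estimated correlation). The count was 0 by limma without mmi1Δ replicate 1 or either array of wild type h+ or ccr4Δ, 1 (rpt6) without mmi1Δ replicate 2, and 342 without slide 1.

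The wild types h+ and smt0 did not differ at any gene by limma, with 84 at an unadjusted p under 0.05. Some levels still lay far apart, chosen here after the values were seen: mag2 had 6.55 ± 0.31 in h+ and 1.62 ± 1.42 in smt0, and SPBC23G7.10C had 6.47 ± 0.16 and 1.49 ± 1.45. Without slide 1, mag2, rpt6, SPBC23G7.10C and SPAC186.04C were called higher in h+, and 8 genes were with slide 1 weighted apart. The Tf2 retrotransposons had a mean of -1.13 in h+ (camera adjusted p = 6.03e-07; adjusted p = 0.584 with an estimated correlation), and the Mmi1 targets -0.19 (camera adjusted p = 0.192). The subtelomeric genes had 0.30, which turned to -0.43 without smt0 replicate 1 and to -0.65 when arrays were scaled by heterochromatin signal. Without smt0 replicate 2, 685 genes were called.

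For the tagged proteins, the first question was which genes each occupied in wild type. Erh1-GFP was highest at mei4, with 2.68 ± 0.24, or 6.40-fold above the array median (adjusted p = 1.12e-05). Next came the ribosomal protein genes rpl3202 and rps2202 (2.52 and 2.42), the transcription factor gene stb3 (2.35), the acid phosphatase gene pho1 (2.28), the RNA export factor gene mlo3 (2.09), the transporter gene tgp1 (1.91) and the RNA helicase gene dbp2 (1.88). CFP-Mmi1 was highest at rps2202, with 2.47 ± 0.06, or 5.53-fold (adjusted p = 6.31e-05), followed by rpl3202 (1.98), mei4 (1.93 ± 0.04), pho1 (1.85), mlo3 (1.80), stb3 (1.75), oga1 (1.69) and dbp2 (1.63). The other 7 of the 15 highest lay between 1.46 and 1.57 for Erh1-GFP (rpl3002, mug45, SPCC1235.01, oga1, mug8, mcp7 and pho84). For CFP-Mmi1 they lay between 1.36 and 1.54 (SPCC1235.01, rpp0, cpc2, tgp1, tef101, rps27 and tef103), and 61.1% and 69.5% of the windows of tef101 and tef103 are repeated elsewhere in the reference.

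The counts of enriched genes were 169 for Erh1-GFP and 280 for CFP-Mmi1 of 4951. Of these, 121 were enriched for both, against 9.56 expected if the 2 sets were independent. That expectation leaves out the shared deviations of same-numbered arrays and any general ChIP signal, so the overlap alone does not show binding of both proteins. The Mmi1 target list had a mean of 0.99 for Erh1-GFP and 0.69 for CFP-Mmi1, with 8 and 7 of 11 enriched; among them, ssm4 had 1.02 and 0.60, num1 1.06 and 0.71, and sme2 0.72 and 0.69. The values at mug9 were 0.73 for Erh1-GFP and 0.58 for CFP-Mmi1, and rec8, mug10 and spo5 were not enriched for either, at 0.05 to 0.27. All 3 phosphate genes were enriched for both, with means of 1.88 and 1.52. Of these, pho84 (II 4446000 to 4447800) and pho1 (II 4449300 to 4450500) lie close together and may not be separate sites. Other genes that lie close together, such as mlo3 and byr2, were also counted apart. Of 114 ribosomal protein genes 25 were enriched for Erh1-GFP and 105 for CFP-Mmi1 (means 0.51 and 0.88), and of 20 glycolytic and other strongly transcribed genes 4 and 8 (means 0.36 and 0.79). Among the 24 other meiotic genes, 1 (rec10) was enriched for Erh1-GFP, and the list means were 0.09 and 0.00. The Tf2 retrotransposons had means of 0.53 and 0.12, the subtelomeric genes -0.26 and -0.46, the 1 measured gene of the silent mating-type region and pericentromeres 0.23 and 0.38, and the factor genes 0.00 for both. Across genes, which are not independent replicates, the means of the 2 proteins correlated at 0.82, the replicate 1 arrays at 0.62 and the replicate 2 arrays, which shared slide 5, at 0.90. Erh1-GFP in mmi1Δ, without Mmi1, still correlated at 0.53 with CFP-Mmi1 in wild type. Without wild type replicate 2 or replicate 1 of Erh1-GFP its count was 101 or 308, and that of CFP-Mmi1 was 100 without its replicate 2.

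The last question was whether Erh1-GFP depends on mmi1. The strains compared also differ at the marker gene ura4. Its input, relative to the median of the arrays, was -6.45 and -5.78 in wild type and 1.17 on both mmi1Δ arrays. An effect of such other strain differences was not tested. In mmi1Δ Erh1-GFP fell at mei4 from 2.68 ± 0.24 to 0.41 ± 0.06, a change of -2.27 (SE 0.16, adjusted p = 0.00158), or 4.81-fold. It fell by a similar size at stb3 (SPBC1652.01, II 4254000 to 4256700), with -2.17 (SE 0.16, adjusted p = 0.00158), and at pho1 (SPBP4G3.02), with -2.15 (SE 0.20, adjusted p = 0.00550). The ribosomal protein genes rps2202 and rpl3202 changed by -2.02 and -1.96 (adjusted p = 0.00231 and 0.00158), and mlo3 by -1.84 (adjusted p = 0.0334). In all, 19 genes fell and 0 rose by limma, with 355 at an unadjusted p under 0.05; with the replicate number as a block 77 were called, 66 lower and 11 higher. Among them were mug45 (-1.46), the kinase gene byr2 (-1.28) and rec10 (-0.99), a component of meiotic linear elements. Within slide 5, which held 1 array of each strain, mei4 had -2.39 and ssm4 -0.97.

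Of the 11 Mmi1 targets 7 fell over all genes and 8 adjusted over the list alone. Besides mei4 these were mcp7 (-1.72), mug8 (-1.51), num1 (-1.15), mug9 (-1.13), crs1 (-1.13) and ssm4 (-0.96, adjusted p = 0.0452); sme2 had -0.91 (adjusted p = 0.360), and rec8, mug10 and spo5 had -0.40 to -0.17. The list mean was -1.06 (camera adjusted p = 7.72e-18; adjusted p = 0.113 with an estimated correlation), with -1.06 within slide 5. The phosphate genes had a mean of -1.48 (camera adjusted p = 3.43e-07; adjusted p = 0.139 with an estimated correlation), with 1 fallen over all genes and 3 adjusted over the list alone. Ribosomal protein genes had -0.29 (camera adjusted p = 1.08e-11; adjusted p = 0.492 with an estimated correlation), with 2 and 6 fallen. The subtelomeric genes had 0.33 (camera adjusted p = 2.1e-14; adjusted p = 0.139 with an estimated correlation), with 0 and 4 risen by limma. The other meiotic genes, Tf2 retrotransposons, glycolytic and other strongly transcribed genes, and factor genes had means of -0.11, -0.05, -0.02 and 0.02, with camera adjusted p from 0.183 to 0.965. In mmi1Δ 0 genes were enriched for Erh1-GFP by limma, with 25 at an unadjusted p under 0.05. Without mmi1Δ replicate 2 the count was 0, and without mmi1Δ replicate 1 it was 4 (mei4, rpl3202, rps2202 and stb3); mcp7, num1, mug9, crs1 and mug45 were also lost without wild type replicate 1. The calls of rec10 and ssm4 also ended without a CFP-Mmi1 array, and with slide as a random block 992 genes were called, 675 of them lower.

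**Figure D4:**
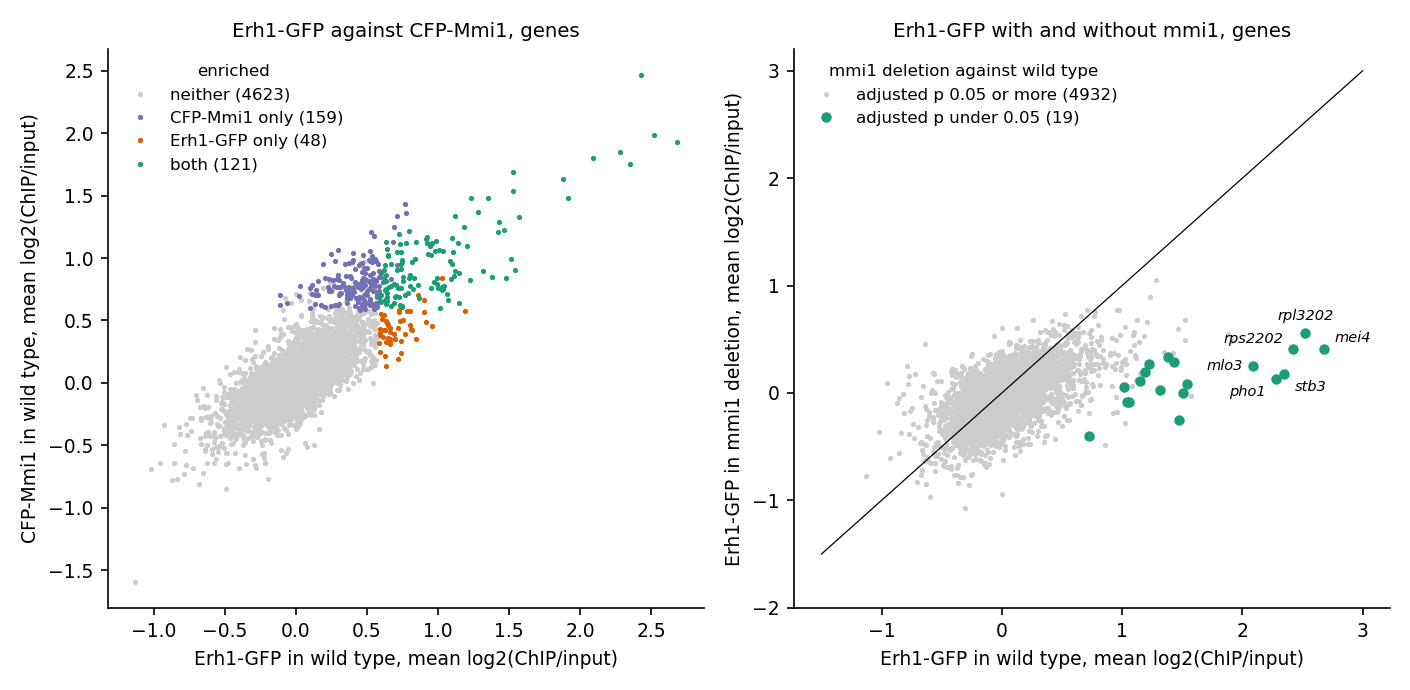
Gene means in log2 ChIP over input (array median 0), with CFP-Mmi1 against Erh1-GFP in wild type on one side and Erh1-GFP in mmi1Δ against wild type on the other, with a line of equality. Colours mark the 121 genes enriched for both proteins and the 19 genes lower in mmi1Δ, such as mei4, which moved from 2.68 to 0.41.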

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

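The tests of slides, of the ChIP channel, of a weaker ChIP and of strongly transcribed genes were chosen only after the results were seen; those of DNA loss and of input copies were written before. The ccr4Δ and mmi1Δ strains were compared directly, and 11 genes differed. That count was 0 by limma under normexp, loess or the replicate block and after scaling by heterochromatin signal. Lower in ccr4Δ were SPAC186.08C (-3.75), SPAC750.01 (-3.54), SPAC977.14C (-3.34) and SPAC186.06 (-3.03), all subtelomeric. Higher in ccr4Δ were 7 genes of the mating-type domain: SPBC23G7.10C (5.25), mag2 (5.16), rpt6 (4.22), sui1 (3.93), the urea transporter gene SPBC23G7.13C (3.58), mas2 (2.61) and ppp16 (2.34). The island over mcp7 (I 579000 to 581100) was higher in ccr4Δ by 2.80, and the mating-type domain (II 2071800 to 2194200) by 2.40. At SPBC23G7.10C the level was 6.47 in wild type h+ and 6.62 in ccr4Δ, and 1.49 in wild type smt0, 1.37 in mmi1Δ and 1.97 in erh1Δ. The strains did not split that way at every one of the 7: at ppp16 wild type smt0 had 2.09, h+ 2.22 and mmi1Δ 0.32. Among the H3K9me2 groups, the input of the marker gene ura4 was lost in wild type h+ (-6.81) and ccr4Δ (-6.20) only. The segment between mat1 and the silent region had 5.70 and 5.86 in that pair. It had 2.29 in wild type smt0, 1.39 in mmi1Δ and 2.08 in erh1Δ. At SPBC23G7.10C and over that segment, each deletion thus lay near the wild type that it resembled at ura4. These values argue against an effect of either deletion there, but not at ppp16, where mmi1Δ lay below both wild types. The mating-type background of each strain was not tested against the deletion.

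The fall of H3K9me2 at 7 subtelomeric genes of chromosome I in ccr4Δ was weighed against 3 technical explanations. Loss of their DNA would lower the input, but the input of the 7 genes was higher in ccr4Δ than on the other H3K9me2 arrays, by 1.09 on average (0.83 and 1.36 per array). A slide difference would vanish within slides, but the fall against wild type h+ was -4.03 on slide 4 and -3.92 on slide 7. A higher input as the whole fall would leave the ChIP channel unmoved, but that channel alone lay at -2.37 against the wild types (-2.76 and -1.98 per array). Part of the fall in the ratio came from the input, which lay 0.78 and 1.31 above the wild types. Why the input was higher, for example through more copies of these sequences, was not tested. An effect of ccr4 itself stays open as a hypothesis. The mean pericentromere change was 0.47, with an SE of 0.50 on average for a single pericentromere. SPAC186.07C was also low in erh1Δ (2.72 against 5.38 and 6.65 in the wild types).

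The fall at the ends of chromosome III in erh1Δ was treated the same way. More copies of these sequences in the input would raise it by about 1 or more, but over the 79 end probes it lay only 0.41 higher (0.36 and 0.47 per array). The fall against wild type smt0 was -2.98 and -2.54 within the slides that hold both strains. A weaker ChIP as the whole fall would lower the pericentromeres as much, but their mean change was -0.40, and -0.09 and -0.19 within the same slides. The SE of a single pericentromere was 0.50 on average, and no SE of their mean was taken. Whether the fall is specific to these ends stays open; the 50 subtelomeric genes had a mean of -0.93 (adjusted p = 0.783 with an estimated correlation) with 0 called over all genes by limma and 9 adjusted over the list alone, and scaling by heterochromatin signal ended the calls (adjusted p = 0.321, the highest over the alternatives), as did leaving out erh1Δ replicate 2 (adjusted p = 0.215 and 0.227), while 21 of 26 alternatives kept them.

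Both tagged proteins gave signal over strongly transcribed genes, which may appear in any ChIP. A signal of that kind would stay in mmi1Δ for Erh1-GFP. The glycolytic and other strongly transcribed genes had a mean change of -0.020, but it was -0.51 without wild type replicate 1 and 0.47 without wild type replicate 2. For the ribosomal protein genes it was -0.29 (adjusted p = 0.492 with an estimated correlation), and -0.52 and -0.065 without the same arrays. For both lists a general ChIP signal and binding through Mmi1 cannot be told apart, since the value depends on which wild-type array is used. Leaving out a wild-type array also breaks the pairs of same-numbered arrays, and differences within pairs are not given here for these lists. An untagged strain was not analysed here.

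Signals outside the comparisons came from the input channel and the deposited table. The input of ura4, a common selection marker, was far below the median of the arrays in wild type h+ (-6.81), ccr4Δ (-6.20), Erh1-GFP wild type (-6.12) and CFP-Mmi1 replicate 2 (-4.95). It was at 0.74 in CFP-Mmi1 replicate 1 and at 1.17 on each array of Erh1-GFP in mmi1Δ. The CFP-Mmi1 arrays thus differ from each other at this locus, as do the strains with Erh1-GFP, and the effect of this was not tested. The input of mmi1 in the CFP-Mmi1 strain was 0.72 above the median of the arrays, and that of the 10 arrays without deleted mmi1 or CFP-Mmi1 lay between -0.15 and 0.22. In mmi1Δ on the H3K9me2 arrays the input of SPAC212.06C lay at -2.35 against the other groups, and 1 mei4 probe (II 1475400) lay at -7.42 relative to the median of the arrays, against 0.23 in mmi1Δ with Erh1-GFP. That probe was left out of the 7 of mei4, and what altered the locus in that strain was not tested; in erh1Δ no mei4 probe was lost. In the deposited table, the column of Erh1-GFP wild type replicate 1 correlated at most at 0.769 with any array, and the column of wild type smt0 replicate 1 at 0.441 with its own array, since the smt0 columns are exchanged.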

How the results depend on the processing

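Tests without slide 1, with slide 1 weighted apart, with slide as a fixed block, with outlier spots kept and without the lowess arrays were chosen only after the data were seen. The H3K9me2 fall of the Mmi1 target list kept its direction and its call under all 28 alternatives in each deletion, from -1.35 to -0.91 in mmi1Δ, -1.46 to -0.90 in erh1Δ and -0.60 to -0.38 in ccr4Δ. The count of 2 genes in mmi1Δ stayed within 1.5-fold under 11 of 28. Where nothing else is said, the cause was not tested. Counts of 0 are by limma, with the count at an unadjusted p under 0.05 given in the report.

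Over mmi1Δ, erh1Δ, ccr4Δ and ccr4Δ against mmi1Δ (2, 2, 7 and 11 genes), normexp gave 0, 0, 0 and 0, loess 0, 1, 0 and 0, the replicate block 0, 1, 2 and 0, scaling by heterochromatin signal 0, 0, 0 and 0, and leaving out the lowess arrays 0, 0, 0 and 0. Fits of the wild types and 1 deletion alone, with fewer arrays, gave 0, 0 and 0 in the deletions. Wild type h+ alone gave 5 in mmi1Δ, wild type smt0 alone 1 in erh1Δ and 2 in ccr4Δ, slide as a random block 5 in erh1Δ, and slide as a fixed block 0 in mmi1Δ and 0 in erh1Δ. Without slide 1 the counts were 318, 0, 34 and 342, and with slide 1 weighted apart 427, 19, 65 and 523. For h+ against smt0, erh1Δ against mmi1Δ and ccr4Δ against erh1Δ (0 each) they were 4, 214 and 14 without slide 1, and 8, 306 and 43 weighted. Leaving out 1 array gave 0 to 2 genes in mmi1Δ, 0 to 4 in erh1Δ, 0 to 7 in ccr4Δ, 0 to 685 between the wild types (685 without smt0 replicate 2), 0 in each case for erh1Δ against mmi1Δ, 0 to 16 for ccr4Δ against mmi1Δ (16 without smt0 replicate 1) and 0 to 1 for ccr4Δ against erh1Δ. The replicate numbers do not pair the H3K9me2 arrays of all groups, since their deviations correlated from -0.33 (smt0 and erh1Δ) to 0.80 (h+ and ccr4Δ). There the block is only an alternative. The numbers do pair h+ with ccr4Δ, which shared slide 4 as replicate 1 and slide 7 as replicate 2, and the block gave 2 genes in ccr4Δ in place of 7. Wild type smt0 and erh1Δ shared slides 1 and 2 with the numbers crossed. The range of mei4 in mmi1Δ over 27 alternatives was -3.96 to -2.16, with adjusted p from 5.28e-06 to 0.712, and that of ssm4 -3.06 to -2.01. Where leaving out arrays leaves 1 in a group, that array is assumed to vary like the other groups. Without slide 1, smt0, mmi1Δ and erh1Δ keep 1 array each. The array of mmi1Δ is then the only array on slide 3, so counts that involve mmi1Δ cannot tell deletion and slide apart.

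The 4 islands of mmi1Δ were 2 with h+ alone, 1 after scaling, 2 without slide 1, 7 weighted, 7 with slide as a fixed block and 2 without the lowess arrays. Of the 7 with slide as a fixed block 1 was higher and 2 were among the 4 (those over ssm4 and num1), while those over mcp7 and mei4 lost their call. The 4 of erh1Δ were 2 with smt0 alone, 2 with h+ alone, 1 with fewer arrays in the fit, 0 after scaling, 1 without slide 1 and 2 without the lowess arrays. Leaving out 1 array gave 1 to 8 in each. In ccr4Δ (0) there was 1 without the probe filter, at the deleted ccr4 locus itself, 1 with slide as a random block (num1), and 0 to 4 when leaving out 1 array, with 4 without smt0 replicate 2. The 19 Erh1-GFP genes were 35 from the deposited table, 77 with the replicate block, which changed no call of a list or named gene in that comparison, 992 with slide as a random block, 9 with the probe median, and 0 to 27 when leaving out 1 array, with 0 without mmi1Δ replicate 2. The Erh1-GFP mean of the Mmi1 target list, -1.06, lost its call with an estimated correlation (adjusted p = 0.113). Enriched genes for Erh1-GFP (169) were 342 with normexp, 48 with a 2-fold threshold and 101 to 308 when leaving out 1 array (101 without wild type replicate 2 and 308 without replicate 1). For CFP-Mmi1 (280) they were 462 with normexp, 152 with at least 4 probes per gene, which tests fewer genes, 59 with a 2-fold threshold and 100 to 306 when leaving out 1 array (100 without its replicate 2).

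Outside these counts, 229 results had 5008 alternative values: 4501 the same, 394 weaker, 80 stronger and 33 reversed, all of the 33 list means. In mmi1Δ Tf2 was -0.45 with slide as a fixed block and -0.19 to 0.62 when leaving out 1 array. The subtelomeric genes there were 0.31 under loess, 1.34 after scaling and 0.73 with slide as a fixed block. In erh1Δ Tf2 was -0.28 with slide as a fixed block and -0.12 to 0.69 when leaving out 1 array. The glycolytic genes there were 0.26 under loess, 0.13 without slide 1 and -0.48 to 0.42 when leaving out 1 array (0.42 without erh1Δ replicate 2). In ccr4Δ Tf2 ranged from -1.52 to 0.27 (0.27 without ccr4Δ replicate 2). For h+ against smt0 the subtelomeric genes were -0.43 without slide 1, -0.65 after scaling and -0.43 to 1.02 when leaving out 1 array, and the ribosomal protein genes -0.11 without slide 1 and -0.11 to 0.77 when leaving out 1 array (both lowest without smt0 replicate 1). For erh1Δ against mmi1Δ Tf2 was -2.49 under loess, and the subtelomeric genes 0.68 without slide 1, 0.56 weighted and -1.31 to 0.41 when leaving out 1 array (0.41 without erh1Δ replicate 2). For ccr4Δ against mmi1Δ Tf2 was 0.088 with normexp, 0.058 without the lowess arrays and -1.74 to 0.058 when leaving out 1 array (0.058 without ccr4Δ replicate 2). For ccr4Δ against erh1Δ Tf2 was 0.26 with normexp and 0.13 under loess, and the subtelomeric genes 0.086 under loess and -1.36 to 0.35 when leaving out 1 array (0.35 without erh1Δ replicate 1). In the same comparison the ribosomal protein genes were -0.046 under loess, -0.026 without slide 1 and -0.026 to 0.79 when leaving out 1 array, and the glycolytic genes -0.29, -0.23 and -0.23 to 0.67 (both lowest without erh1Δ replicate 2). For Erh1-GFP in mmi1Δ Tf2 was 0.12 from the deposited table, and the glycolytic genes -0.51 to 0.47 when leaving out 1 array (0.47 without wild type replicate 2). Slide as a fixed block could not be estimated against the mean of both wild types or for the tagged proteins and was not run there. The ChIP channel was well above background for 94.3% of probes on ccr4Δ replicate 2, the lowest of the arrays.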

Other observations

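The test of whether the fallen islands lay over genes with Erh1-GFP was chosen before its result was seen; the region values were singled out only after the data were seen, with no tests of their own. Over the segment between mat1 and the silent region (II 2116800 to 2130000, 45 probes) H3K9me2 was 5.70 ± 0.20 in wild type h+ and 5.86 ± 0.19 in ccr4Δ, and 2.29 ± 0.83 in wild type smt0, 1.39 ± 1.11 in mmi1Δ and 2.08 ± 0.71 in erh1Δ. The silent region itself (II 2130300 to 2139900) had 6.27 ± 0.45 and 6.62 ± 0.50 in the first pair and 5.31 ± 1.24, 4.55 ± 0.31 and 4.71 ± 1.43 in the other strains. There the arrays of smt0 and erh1Δ on slide 1 had 4.44 and 3.70, and those on slide 2 had 6.19 and 5.72, against 5.95 and 6.59 in the h+ arrays. In mmi1Δ the array on slide 1 had 4.77 and that on slide 3 had 4.33, so a low value was not limited to slide 1. The pericentromere of chromosome I had 6.35 ± 0.59 in wild type h+, 6.55 ± 0.78 in ccr4Δ, 5.18 ± 1.99 in wild type smt0, 5.19 ± 0.01 in mmi1Δ and 5.15 ± 1.77 in erh1Δ. The smt0 and erh1Δ arrays on slide 1 had 3.77 and 3.89 there, and those on slide 2 had 6.59 and 6.40, within the h+ arrays at 5.93 and 6.76. The telomere clone probes had 3.63 to 3.93 over the H3K9me2 groups, and the mitochondrial probes, which carry no histones, -3.38 to -2.39.

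One hypothesis was that H3K9me2 islands that depended on mmi1 and erh1 lay where Erh1-GFP sat in wild type. All 4 islands that fell in both deletions overlapped a gene enriched for Erh1-GFP, against 10 of the other 120 islands (Fisher's exact two-sided p = 0.000107). This is consistent with the hypothesis, but Erh1-GFP may also have been called at more genes than it binds, and the 4 islands were found in these data. Among the 10 other islands with an Erh1-GFP gene were those over mug9, over byr2, mlo3 and clg1, and over rps1502 and pma1. The island over rps1502 and pma1 (I 3843600 to 3871200) lies near the pericentromere of chromosome I, and the test did not account for nearness to constitutive heterochromatin.

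The input channel showed each deleted gene as lost in whole or in part. Of the mmi1 probes 6 of 10 were lost in both mmi1Δ strains, of the erh1 probes 2 of 2 in erh1Δ, and of the ccr4 probes 7 and 6 of 7 in the arrays of ccr4Δ. Averaged over lost and kept probes, the input of mmi1 lay at -4.75 in mmi1Δ of the H3K9me2 arrays and -4.29 in mmi1Δ of the Erh1-GFP arrays, that of erh1 at -8.49 in erh1Δ and that of ccr4 at -8.39 in ccr4Δ, against the other groups.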
